A study of Homo sapiens with 6 samples.

How the data were processed

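Total RNA of 6 samples of A549 cells was measured, 3 labelled NANOG-positive and 3 labelled NANOG-negative. Per the labels' protocols, RNA quality was judged by spectrophotometer and gel, ribosomal RNA was removed, and RNA was amplified by random priming along whole transcripts and labelled with Cy3. Nothing in the labels says that the samples of a group came from separate cultures. The p-values therefore rest on the spread between these samples, which may be technical. The replicate numbers in the labels name samples and were not used to pair them.

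Each array gave a table of spot intensity values (processed signal, median signal and median background), which the scanner software made before they were deposited. Per the file headers, the software was Agilent Feature Extraction 11.0.1.1 with a 1-colour protocol, which had subtracted background and corrected spatial trends within each array and had applied no scaling between arrays. The deposited series table held log2 values per probe. Its 6 columns had medians of 5.03, and its minimum was 2.32. Across probes the columns correlated at r = 0.999 with quantile-normalised processed signal and at 0.997 to 0.99985 with log2 processed signal, which does not tell these apart. The equal medians point to a normalization between arrays, whose kind is not given in the sources used here. It covered 60495 probes and no panel probe, so it served as an alternative for counts of probes only. The array design was annotated on hg19, per the file headers. No coordinates are printed, since the gene table used for names is of another assembly, GRCh38.p14.

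Processed signals were converted to log2 and each array's 75th percentile over spots that are not controls was subtracted. Control spots were left out, as were 182 further probes with control names, and spots marked as outliers. The spots of a probe were averaged, which left 60546 probes. A probe was tested when it was well above background on at least 3 of the 6 arrays, which 36251 were. Groups were compared with limma (lmFit and eBayes, without covariates, all 6 arrays in 1 fit), and p-values were adjusted by Benjamini-Hochberg over all tested probes, with 0.05 as the threshold. All adjusted p-values in the text are from limma. Each SE and p-value uses a spread that eBayes draws towards the spread common to all tested probes. For panel genes with close replicates the SE is therefore not their own spread. BRCA1, for example, had an SE of 0.042 with SDs of 0.017 in NANOG-positive and 0.016 in NANOG-negative samples. Differences are NANOG-positive minus NANOG-negative. Control probes were fitted together with the tested probes. R 4.3.3, limma 3.58.1, the data.table package (version 1.17.8), jsonlite 2.0.0 and matplotlib 3.10.9 were used.

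The files pair no probe with a gene symbol. For 50 probes they give a transcript accession, each with 10 spots, and 49 accessions matched a symbol in the gene table when versions were ignored. No gene had more than 1 such probe. The remaining probes were grouped by letters in their identifiers. LNC was read as long noncoding RNA, and AP1B and V4 are used as names without a class. Before the data were examined, the rule for named genes was set as NANOG, then the 12 largest differences each way among protein-coding probes. These had to pass the threshold with no overlap between groups and be above background in the higher group. Up to 4 members were allowed of a list that passed its test or had at least 3 passing members. Of other lists, up to 2 with the smallest adjusted p were allowed. ZNF195, PRIM1, CHAF1B, CENPE and genes that did not pass and belong to no list fall outside that rule. They were chosen after their values were seen, as were the probes given by identifier, which had the 2 highest and the 2 lowest measured log2 differences.

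The lists fixed before the data were examined numbered 41 and covered pluripotency, stem cell markers, lineage, signalling, stress, cell cycle, metabolism, immune genes, markers of other cell types and named long noncoding RNAs. Of these, 6 had a named gene on the panel and 35 had none, so stem cell and pluripotency markers were not analysed here. A set test needed 5 tested members, and the most in any list was 3.

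Slides were taken from the file headers and were 2 in number. The fit was repeated with the slide as a block and within slide 2, which holds 1 NANOG-positive and 3 NANOG-negative arrays. In data simulated on the spread of 36231 probes for this comparison, the fit recovered 28 of 100 probes changed by 0.5 log2 units and 66 of 100 changed by 1, with 6 false calls. With the slide as a block it recovered 0 of 100 at either size. The simulation changed a far smaller share of probes than the 24.2% that passed in the data, where the slide-block fit gave 65 calls. It therefore does not measure the power of that fit on these data. An absent call in that fit does not show an unchanged gene.

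Probes were also divided into sixths of mean signal, and the median difference of each family was taken per sixth. The family comparison at matched brightness used, per array, the mean over the sixths of the difference between family medians. Families may still differ in brightness within a sixth. Alternatives were quantile normalization, scaling on the median of probes above background on all arrays, normexp background correction with an offset of 50 on the median signal, no filter on dim probes, a filter on all 6 arrays, the deposited series table, an intensity trend with a robust prior, the replicate number or the slide as a block, 2-fold thresholds, and each array left out in turn.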

Results

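RNA from A549 cells, a human lung adenocarcinoma line, was hybridised to 1-colour Agilent arrays that carry probes for mRNAs and long noncoding RNAs. The labels split the 6 samples into 3 NANOG-positive samples, which they call cancer stem cells, and 3 NANOG-negative samples, which they call non-stem cells. NANOG is a transcription factor of pluripotent cells. Each array held 62921 spots, of which 60996 were not control spots, and none of these 60996 was saturated. Probes well above background made up 62.1% ± 1.29 of the probes in the NANOG-positive samples and 55.7% ± 2.78 in the NANOG-negative samples (SD, n = 3 each). Pearson correlations across probes ran from 0.995 to 0.996 within the NANOG-positive group, from 0.993 to 0.995 within the NANOG-negative group, and from 0.990 to 0.993 between the groups. The number of arrays limits the precision of each value given here.

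The comparison asked how the mRNA and long noncoding RNA levels of the NANOG-positive population differed from those of the NANOG-negative population. Of the 6 tested genes of the S phase and mitosis lists, 4 were lower in NANOG-positive cells and 2 did not pass. CCNA2, which encodes cyclin A2 of S and G2 phase, was 1.34-fold lower (log2 difference −0.43, SE 0.044, adjusted p = 0.00631, n = 3 against 3). EXO1, an exonuclease of DNA mismatch repair, fell by 0.40 on the log2 scale (SE 0.045, adjusted p = 0.00669), and KIF20A, a mitotic kinesin, fell by 0.35 (SE 0.043, adjusted p = 0.00806). PLA2G4A, the cytosolic phospholipase A2 that releases arachidonic acid, had the largest decrease, 1.39-fold (log2 difference −0.48, SE 0.043, adjusted p = 0.00566). PPIP5K2, a kinase that makes inositol pyrophosphates, had the largest increase, 1.44-fold (log2 difference 0.52, SE 0.045, adjusted p = 0.00524). In each of these 5 genes the 3 NANOG-positive arrays lay apart from the 3 NANOG-negative arrays. The genes with the largest decrease and increase were so ranked among the 44 named genes that were tested, and under the main scaling only. Under quantile normalization COL13A1 (0.42) was above PPIP5K2 (0.32). SPDL1 was at −0.55 there, while PLA2G4A was no lower than −0.52 under any of 3 other scalings.

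Gene names were given by 50 probes with a transcript accession, each printed in 10 spots, and 49 of these matched a gene symbol, all of protein-coding genes. Of the 44 named genes that were bright enough to test, 22 passed an adjusted p of 0.05 over all probes, 7 higher and 15 lower in NANOG-positive cells. Adjusted over the panel alone, 24 of the 44 passed. The groups did not overlap in 40 of the 44 genes (90.9%), where chance gives 10% for a single gene. All these genes were measured on the same arrays and are not independent, so the share is no test of the grouping. Small differences also counted, such as −0.04 for DNTTIP2 and −0.04 for WRN, neither of which passed. The share without overlap over all tested probes was not computed, while 24.2% of them passed the threshold. Panel probes average 10 spots each, and of the 45 tested 15 lay in the fifth and 26 in the brightest sixth of mean signal. The high shares are therefore not shown to be particular to these genes. CD69, CFTR, LOX, SAA4 and ZAP70 were not well above background on any array. No probe was paired with NANOG in the sources used here, so its level was not analysed here.

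**Figure D1:**
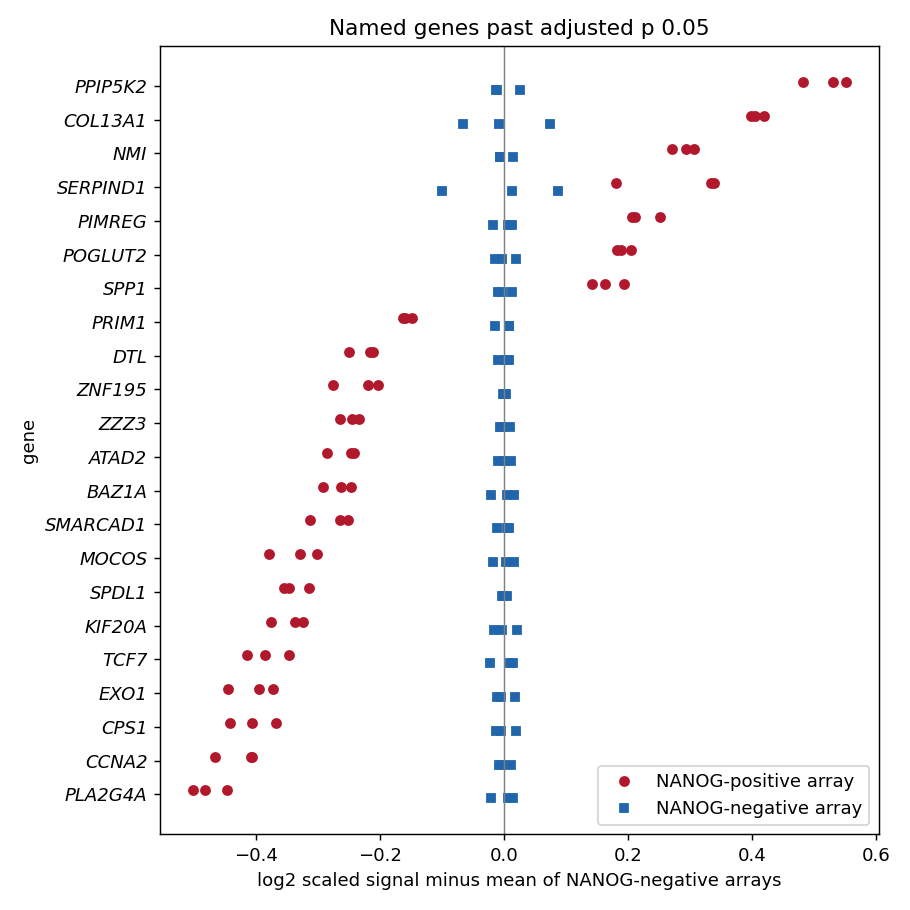
Log2 scaled signal of the 22 named genes that passed an adjusted p of 0.05, each array drawn as its difference from the mean of the NANOG-negative arrays of that gene (circles, 3 NANOG-positive arrays; squares, 3 NANOG-negative arrays; horizontal axis in log2 units, 1 gene per line). The groups do not overlap in any of these genes, 15 lie lower and 7 higher, and SPP1 turned to −0.05 under quantile normalization.

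Of the lists of genes fixed before the data were examined, the DNA replication and S phase list had 3 tested members, and 2 of them fell. These were EXO1 and DTL, a substrate receptor of the CUL4 ubiquitin ligase, which fell by 0.23 (SE 0.042, adjusted p = 0.0173), with −0.20 (adjusted p = 0.128) under normexp background correction. CHAF1B, a subunit of the chromatin assembly factor that loads histones on new DNA, was at −0.11 (SE 0.042, adjusted p = 0.119), and at −0.28 (adjusted p = 0.0282) under quantile normalization. Adjusted over the list alone, 3 members were lower. In the mitosis and G2/M list, CCNA2 and KIF20A fell and CENPE, the centromere-associated kinesin, was at −0.08 (SE 0.047, adjusted p = 0.287). Adjusted over the list alone, 2 of its 3 members were lower. TCF7, the transcription factor of the Wnt pathway list, fell by 0.38 (SE 0.044, adjusted p = 0.00718), with −0.24 (adjusted p = 0.0546) under normexp background correction. COL13A1, a transmembrane collagen and the member of the matrix list on the panel, was higher by 0.41 (SE 0.053, adjusted p = 0.00855). LOXL2, a lysyl oxidase on the hypoxia list, was at −0.08 (SE 0.041, adjusted p = 0.191), and at −0.36 (adjusted p = 0.0178) under quantile normalization. LOX, a member of the hypoxia and mesenchymal lists, was below background. With at most 3 tested members per list, no list was tested as a set.

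Lower genes that belong to no list on the panel are given singly. SPDL1, a kinetochore protein that recruits dynein, fell by 0.34 (SE 0.041), and PRIM1, the catalytic subunit of DNA primase, fell by 0.16 (SE 0.041). The ATPase SMARCAD1 fell by 0.28 (SE 0.043), the remodelling subunit BAZ1A by 0.27 (SE 0.043), the bromodomain ATPase ATAD2 by 0.26 (SE 0.042) and ZZZ3 by 0.25 (SE 0.041). CPS1, the mitochondrial carbamoyl phosphate synthetase of the urea cycle, fell by 0.41 (SE 0.045), and MOCOS, the molybdenum cofactor sulfurase, fell by 0.34 (SE 0.045). ZNF195, a zinc finger gene, fell by 0.23 (SE 0.044). The adjusted p of these genes ran from 0.00668 for CPS1 to 0.0423 for PRIM1. Some sizes depended on the scaling: over 3 other scalings BAZ1A ran from −0.46 to −0.26, ATAD2 from −0.45 to −0.23 and PRIM1 from −0.28 to −0.13. Of the 22 genes that did not pass, BRCA1 was at 0.00 (SE 0.042, adjusted p = 0.964) and at −0.15 (adjusted p = 0.104) under quantile normalization.

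Higher in NANOG-positive cells, after PPIP5K2 and COL13A1, were NMI, a partner of MYC and STAT proteins (0.29, SE 0.041), SERPIND1, which encodes heparin cofactor II (0.28, SE 0.075), PIMREG, a regulator of mitosis (0.22, SE 0.043), POGLUT2, a protein O-glucosyltransferase (0.19, SE 0.041), and SPP1, which encodes osteopontin (0.17, SE 0.042). Their adjusted p ran from 0.0102 for NMI to 0.0433 for SERPIND1. Under quantile normalization the 15 lower genes, PPIP5K2, COL13A1 and SERPIND1 kept direction and call, NMI (0.06), PIMREG (0.05) and POGLUT2 (0.06) lost the call, and SPP1 turned to −0.05 (adjusted p = 0.625). That scaling moved the median of the tested panel genes from −0.08 to −0.25, so the split of 7 higher and 15 lower became 3 higher and 23 lower among 26 calls, 18 of them among the 22 genes. With normexp background correction 9 of the 22 genes passed, namely PPIP5K2, NMI, CCNA2, EXO1, KIF20A, PLA2G4A, SPDL1, CPS1 and MOCOS, while COL13A1 stood at 0.20 (adjusted p = 0.143) and SERPIND1 at 0.19 (adjusted p = 0.116). When 1 array at a time was left out, POGLUT2, SPP1 and PRIM1 lost the call each time, SERPIND1 5 times, PIMREG 4 times, DTL and ZNF195 3 times, ZZZ3, ATAD2 and BAZ1A 2 times and SMARCAD1 1 time, with adjusted p up to 0.125. These 11 genes and NMI also lost it without a filter on dim probes (adjusted p 0.0534 to 0.101).

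The slides were not balanced between the groups, since NANOG-positive samples 1 and 2 lay on slide 1 and NANOG-positive sample 3 shared slide 2 with the 3 NANOG-negative samples. With the slide as a block, PPIP5K2 stood at 0.48, PLA2G4A at −0.50 and SERPIND1 at 0.18, and limma called 0 of the 44 genes at an adjusted p of 0.05 and 20 at an unadjusted p of 0.05 (adjusted p from 0.0576 to 0.273 for the 22 genes). The estimate within slide 2 is the same difference, since slide 1 holds samples of 1 group.

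Across the whole array, 8785 of 36251 tested probes (24.2%) passed, 5628 higher and 3157 lower in NANOG-positive cells. The higher share was 64.1%, and under quantile normalization it was 45.2% of 7255 calls. Most differences were small: 211 probes also reached 2-fold under the main scaling, 201 higher and 10 lower. Some of these were not well above background in 1 group, where the measured difference is no size. Well above background in all arrays of 1 group only were 955 probes for NANOG-positive and 2 for NANOG-negative. The 2-fold split may therefore depend on detection. The count of changed probes was 3042 with normexp background correction, 2488 without a filter on dim probes and 65 with the slide as a block. Leaving out 1 array gave between 3384 (without NANOG-negative array 2) and 6583 (without NANOG-positive array 3).

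Among the probes with LNC in their identifier, taken as the long noncoding RNA set, 3384 of 15511 (21.8%) passed, 2433 higher and 951 lower. A second family, with AP1B in the identifier, had 4352 of 15656 probes (27.8%) past the threshold, 2458 higher and 1894 lower, and a further family, with V4 in the identifier, had 1027 of 5039 (20.4%), 730 higher and 297 lower. The RNA class of the AP1B and V4 families is not given in the sources used here. The share of calls that were higher was 71.9% for LNC, 56.5% for AP1B and 71.1% for V4 probes, and under quantile normalization 55.1%, 34.4% and 61.2%. With the slide as a block 23 LNC, 26 AP1B and 16 V4 probes passed, with normexp 1218, 1462 and 353, and 1313, 1650 and 409 when NANOG-negative array 2 was left out.

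At matched brightness the LNC probes lay 0.022 ± 0.0046 log2 units above the AP1B probes in the NANOG-positive arrays and at −0.021 ± 0.0027 in the NANOG-negative arrays (SD, n = 3 each), measured as the median deviation from each probe's mean over the 6 arrays. The difference of 0.043 had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays can give. For V4 probes against AP1B probes the difference was 0.073, with the same exact p of 0.1. Both differences kept their sign under the other scalings. Median scaling could not change them, since it shifts all probes of an array alike. Under quantile normalization they were 0.043 and 0.072, and under normexp background correction 0.033 and 0.058. Brightness was matched by sixth only, so a difference in brightness between families within a sixth was not removed.

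Probes without a gene name here were chosen after their values were seen, as the 2 highest and the 2 lowest measured log2 differences. Each rests on 1 spot per array. The measured difference is no size where a group was not well above background, so this order does not rank the bounds. ASHG19LNC1A100088843V5, of the LNC family, was well above background on the 3 NANOG-negative arrays and on none of the NANOG-positive arrays. Its level was at least 25.1-fold lower in NANOG-positive cells (adjusted p = 3.1e-05, and 0.00406 with the slide as a block). ASHGV40024708V5 was at least 2.92-fold lower in NANOG-positive cells (adjusted p = 0.00764, and 0.0576 with the slide as a block). In the other direction, ASHG19LNC1A100016145V5 was at least 3.88-fold higher (adjusted p = 0.000723) and ASHG19AP1B100175353V5 at least 3.40-fold higher (adjusted p = 0.00118), each with an adjusted p of 0.0383 with the slide as a block. These bounds set the mean of the brighter group against the lowest signal well above background on the arrays of the dimmer group, or the probe's own signal where that was higher.

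The median difference depended on brightness. In the brightest sixth of the tested probes it was 0.19 for AP1B, 0.25 for LNC and 0.32 for V4 probes, and −0.05 for the panel probes there. In the fourth sixth it was −0.05 for AP1B, 0.01 for LNC and 0.06 for V4 probes. Under quantile normalization the medians of the brightest sixth were −0.02 for AP1B, 0.04 for LNC and 0.10 for V4 probes, so the sign for AP1B turned.

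**Figure D2:**
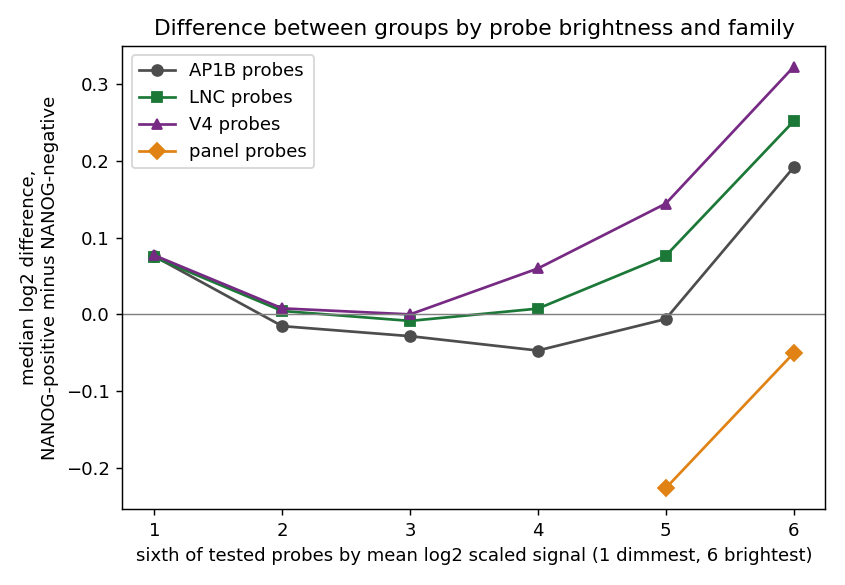
Median log2 difference, NANOG-positive minus NANOG-negative, of tested probes in sixths of mean log2 scaled signal (1 dimmest, 6 brightest), for the AP1B, LNC, V4 and panel families (panel points are drawn for sixths with at least 10 probes). In the brightest sixth the medians are 0.19, 0.25 and 0.32 for AP1B, LNC and V4 and −0.05 for the panel, with AP1B at −0.02 under quantile normalization.

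PGK1 and GAPDH, enzymes of glycolysis, were also measured by control probes at both ends of their transcripts, and these stood outside the tested set. PGK1 fell at its 3′ probe by 0.24 (SE 0.042, adjusted p = 0.0147) and at its 5′ probe by 0.31 (SE 0.044, adjusted p = 0.0101). GAPDH was at −0.06 at its 3′ probe (SE 0.045, adjusted p = 0.353) and at −0.13 at its 5′ probe (SE 0.044, adjusted p = 0.085). Under quantile normalization GAPDH also passed, at −0.24 (adjusted p = 0.0185) and −0.41 (adjusted p = 0.00989), and with normexp background correction the 3′ probe of PGK1 no longer did (−0.23, adjusted p = 0.101). The 5′ minus 3′ log2 signal, a measure of RNA integrity and labelling, was −1.96 ± 0.033 for GAPDH in NANOG-positive samples and −1.89 ± 0.046 in NANOG-negative samples, and −6.31 ± 0.028 and −6.24 ± 0.011 for PGK1 (SD, n = 3 each, exact two-sided permutation p = 0.1 for each gene, the smallest possible).

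More probes were detected only in NANOG-positive samples than the reverse. Well above background on all 3 NANOG-positive arrays and on no NANOG-negative array were 955 of 60546 probes, and 2 probes had the reverse pattern. The lowest signal called well above background was 14.3 to 16.0 on the NANOG-positive arrays and 18.3 to 24.9 on the NANOG-negative arrays.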

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

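The test on panel probes of like brightness, the count of splits, and the simulated and array-disjoint forms of the axis test were chosen after the result was seen, and the reading of the detection test was changed then.

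Of the control probes outside the comparison, 7 stood apart because they were bright on all 6 arrays and passed the threshold with a level over 0.5 log2 units higher in the NANOG-positive arrays, without overlap between the groups. This rule sought higher probes only. ASSPINKEIN100004726 was higher in NANOG-positive arrays by 0.997 (SE 0.23) and the external control ERCC-00097_63 by 0.963 (SE 0.23). The latter stood at 0.35, −0.58 and −0.13 on NANOG-positive arrays 1, 2 and 3. ASSPINKEIN100003625 was higher by 0.64, ERCC-00062_278 by 0.53, ASSPINKEIN100008616 by 0.53, ASSPINKEIN100003643 by 0.51 and ASSPINKEIN100001298 by 0.51. Of the other 2 bright ERCC probes, ERCC-00012_90 passed lower (−0.24, adjusted p = 0.0487) and ERCC-00043_129 was at −0.01. Over the bright control probes, the median difference was 0.13 for 29 ASSPINKEIN probes and −0.30 for 7 probes of rodent genes, of which 5 passed, all lower. Among these, the 3′ probe of mouse PGK1 was at −0.52 (adjusted p = 0.0054), the same way as the human PGK1 probes. It was bright on all 6 arrays without overlap between the groups, so it would meet the same rule in the other direction.

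Many probes differed between the groups, and the slides only partly overlapped with them. If the slide alone made the difference, the NANOG-positive array on slide 2 would lie with the NANOG-negative arrays beside it. Its difference from a single NANOG-negative array was set against the difference of the slide 1 arrays from the other NANOG-negative arrays. The slope across probes was 0.487, 0.557 or 0.586, depending on the array left for the comparison, which argues against the slide as the whole source. A partial share of the slide stays open, and so does the difference between the populations, which the design names. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave any calls, with 8785 probes, 22 named genes, 3384 LNC, 4352 AP1B and 1027 V4 probes, while the highest other split gave 0 in each case. With 10 splits the share cannot fall under 0.05. Each other split also mixes the groups, which puts any difference between them into the residual spread and lowers the calls, whatever its cause. The counts of the other splits therefore do not decide on chance or on a cause.

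The brightest probes leaned towards NANOG-positive cells. A single intensity response for all bright probes would shift the named genes as well, but the 25 named genes in that sixth had a median of −0.0598 (95% bootstrap interval −0.11 to 0.07), against 0.19 for probes of the other families of like brightness and 0.15 for AP1B probes alone. The interval lay below both of these values, but that bound was chosen after the value was known. It did not stay under the 0.05 first set, so the test does not decide on such a response. Of the 26 panel probes in that sixth, 11 passed the threshold themselves, so they are no neutral reference. An axis that varies between arrays of 1 group may account for part of the lean: NANOG-positive array 1 minus arrays 2 and 3 followed the difference of arrays 2 and 3 from the NANOG-negative arrays at r = 0.419 across 6010 probes, where 100 simulations with independent noise gave −0.203 to −0.100. With array 2 or 3 in the place of array 1 it was −0.626 or −0.349, below the simulated range. Contrasts that share no array gave r = 0.525 (array 1 minus 2 with array 3 minus the NANOG-negative arrays) and 0.408 (array 1 minus 3 with array 2), against −0.048 to 0.048 in simulation, and −0.183 for array 2 minus 3 with array 1. Scaling stays open: its test was set aside after the value was seen, because quantile normalization equalises the distributions by construction and so largely fixes the median of 0.01 it left in that sixth.

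Detection in all NANOG-positive and no NANOG-negative samples held for 955 probes, 2 showed the reverse, and the highest other split gave 157 in both directions together, against 957. Whether a higher detection limit on the NANOG-negative arrays or a true difference made this pattern cannot be told apart. Raising each value to the highest limit of any array left 18 of the 955 probes (1.88%) with a difference over 0.5 log2 units, but that step also removes true differences of dim probes. The measured median difference of the 955 probes was 0.44, and they were chosen for being brighter in NANOG-positive samples.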

How the results depend on the processing

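The AP1B and V4 counts, normexp on the median signal, the fit within slide 2 and values raised to the detection limit were chosen after seeing the data. The NANOG difference was not run, since no probe is paired with it, nor were set tests of lists, normexp on the mean signal (a column not used here) or a block of scan date, of which there was 1. Counts stayed within 1.5 times under quantile normalization, median scaling, the filter on all 6 arrays, the series table where it applied, the intensity trend and raised values.

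Changed probes fell to 3042 with normexp, 2488 without a filter, 65 with the slide as a block, 1 with the replicate block, 1 within slide 2, 211 at 2-fold and 269 at an unadjusted p and 2-fold. In the same order, LNC counts were 1218, 989, 23, 1, 1, 77 and 110, AP1B counts 1462, 1150, 26, 0, 0, 83 and 96, and V4 counts 353, 339, 16, 0, 0, 51 and 63. Named genes numbered 9 with normexp and 10 without a filter, and limma called 0 with the slide block, the replicate block and within slide 2 (20, 23 and 20 at an unadjusted p of 0.05) and 0 at 2-fold. The block and single-slide fits have fewer residual degrees of freedom, and without a filter more probes were tested. The cause of the normexp counts was not tested. SPP1 reversed to −0.046 under quantile normalization, and no other named gene that passed changed sign in any alternative. Of the 22 named genes that did not pass, 7 gained a call with the same sign under quantile normalization and 7 with raised values, 4 with the intensity trend and 2 with the filter on all 6 arrays, and NOC3L passed under quantile normalization at −0.23 against 0.01.

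Leaving out 1 array gave 3384 to 6583 changed probes, 11 to 19 named genes, 1313 to 2519 LNC, 1650 to 3273 AP1B and 409 to 772 V4 probes. All probes numbered 5704, 5118 and 6583 without NANOG-positive array 1, 2 or 3, and 3992, 3384 and 3430 without NANOG-negative array 1, 2 or 3. Named genes fell to 12 and 11 without NANOG-negative array 2 or 3. Deviations of same-numbered samples from their group means correlated at −0.04, −0.11 and −0.14. No NANOG-positive sample correlated best with its own number. This gives no sign that the numbers pair the samples, but with 3 arrays per group it cannot exclude it. Signal over background limits what can be tested, and 36251 of 60546 probes were bright enough.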

Other observations

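Beside the list members given above, some panel genes that also act in mitosis stand on neither the S phase nor the mitosis list. They come from no fixed set. SPDL1 was at −0.34 and PIMREG at 0.22, while CENPQ (0.12, limma adjusted p = 0.103) and ITGB3BP (0.05, limma adjusted p = 0.431) did not pass. Under quantile normalization SPDL1, PIMREG and CENPQ were at −0.55, 0.05 and 0.03. Within slide 2, from arrays that also enter the full comparison, the list members were at −0.41 for CCNA2, −0.45 for EXO1, −0.38 for KIF20A, −0.25 for DTL, −0.11 for CENPE and −0.10 for CHAF1B, and none passed with the slide as a block.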
